A study of Mus musculus with 18 samples.

How the data were processed

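The samples were endothelial (GFP-positive) and non-endothelial (GFP-negative) cells sorted from pooled retinas of Tie2-GFP mice at postnatal day 8. Per the labels' protocols, total RNA was isolated, amplified, labelled with biotin and hybridised to Affymetrix MGU74v2 arrays in 1 colour. Each population had 3 arrays on each of the 3 chips of that series, A, B and C, and groups and replicate numbers were taken from the sample titles. The deposited values are linear intensities per probe set, 0 or above. The method by which the authors summarised probes into probe sets, corrected background and normalized is not given in the sources used here, and it could change every difference. Within each chip the array medians lay within 0.3 on the log2 scale of one another (ranges 0.0307, 0.0956 and 0.0546 for A, B and C), so the deposited intensities were taken as scaled between arrays and kept. Detection calls and control probe sets were not used here, so neither a check of RNA degradation by control probe sets nor a presence filter was run, and the intensity of a dim probe set may be background.

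Probe sets were named through the platform annotation. On chip A 10833 probe sets had 1 gene symbol, 396 had several and 1193 none, on chip B 10581, 178 and 1652, and on chip C 7717, 150 and 4001. Entrez identifiers of 10817, 10550 and 7677 probe sets matched the mouse RefSeq gene table, and 0 symbols changed. No gene was named from a probe set with several symbols. Each chip was fitted alone, because the chips hold different probe sets and were tabulated separately. The values were transformed to log2 of intensity plus 16 and compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment within the chip and a threshold of 0.05. No replicate block was used. The median log2 difference over all probe sets was 0.0149, 0.0886 and 0.0457 on chips A, B and C.

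A set of 33 gene lists was fixed before the data were examined, covering endothelial identity and subtypes, signalling and guidance pathways, matrix, barrier, metabolism, proliferation, the other cell types of the retina and blood, and dissociation stress. A gene was measured by 1 probe set, the one with the highest mean level among those with its symbol alone, on the first of chips A, B and C that held it. Members without such a probe set were not analysed here. Lists with at least 5 genes on a chip were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of that chip. Camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, in 1 direction without comparing them with other genes, were alternatives. A gene can belong to more than 1 list.

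The genes named in the text followed a rule set before the data were examined. On each chip it took called probe sets with 1 symbol whose populations did not overlap, with the largest differences, 8 in each direction on chip A and 3 in each direction on chips B and C. In each list it took up to 3 called members in the direction most called members took, up to 2 in the other direction and the brightest member that did not pass. Tek, Plxnd1, Rhoj, Pecam1, Kdr, Pdgfrb and Ptprc were always included.

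The fit was tested on simulated data built from the spread of the real arrays with 200 changed probe sets per chip. It recovered 68%, 66% and 75% of changes of 1 on the log2 scale and 94%, 93% and 91% of changes of 2 on chips A, B and C, with 11, 9 and 6 false calls among 12422, 12411 and 11868 probe sets. These were 6.36%, 5.36% and 3.49% of the calls. The simulated noise was independent between probe sets, and no array stood apart. The simulation therefore does not measure false calls in the real data. The alternatives were quantile normalization, median-centred arrays, pseudocounts of 1 and 64, brighter probe sets only, limma-trend with robust eBayes, the replicate number as a block, adjustment over all 3 chips, omission of probe sets that can match several transcripts, an adjusted p under 0.01, a minimum of 2-fold, and each array left out in turn. Array weights were added after GFP-positive replicate 3 had been seen to stand apart. Figures were drawn with matplotlib 3.10.9.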

Results

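Endothelial cells line the growing vessels of the retina, and at postnatal day 8 the vascular network of the mouse retina is still expanding. Retinas of FVB/N mice that carried GFP under the Tie2 promoter, which is active in endothelial cells, were dissociated with papain and sorted by flow cytometry. GFP-positive cells represented the endothelium and GFP-negative cells the remaining retinal cells. Amplified RNA from each population was hybridised to the 3 Affymetrix MGU74v2 chips, named A, B and C, with 3 arrays per population and chip, which gave 18 arrays. The chips held 12422, 12411 and 11868 probe sets, and their array medians ranged from 43.3 to 44.5, from 40.7 to 44.6 and from 32.5 to 34.4 intensity units. The number of arrays limited the precision. The labels do not state that the 3 arrays of a population came from separate animals, so the p-values measure only the spread between these arrays, which may be technical.

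GFP-positive replicate 3 stood apart from the other arrays of its population. On the 3 chips its Spearman rank correlation with GFP-positive replicates 1 and 2 lay between 0.911 and 0.929, whereas all other pairs of arrays of 1 population lay between 0.960 and 0.987 across probe sets. Across the 3 chips, 445 probe sets were at least 4-fold brighter on this array than on the mean of replicates 1 and 2. Of the 160 probe sets named by rule, 9 passed only without this array, and those named below are given with their values without it.

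**Figure D1:**
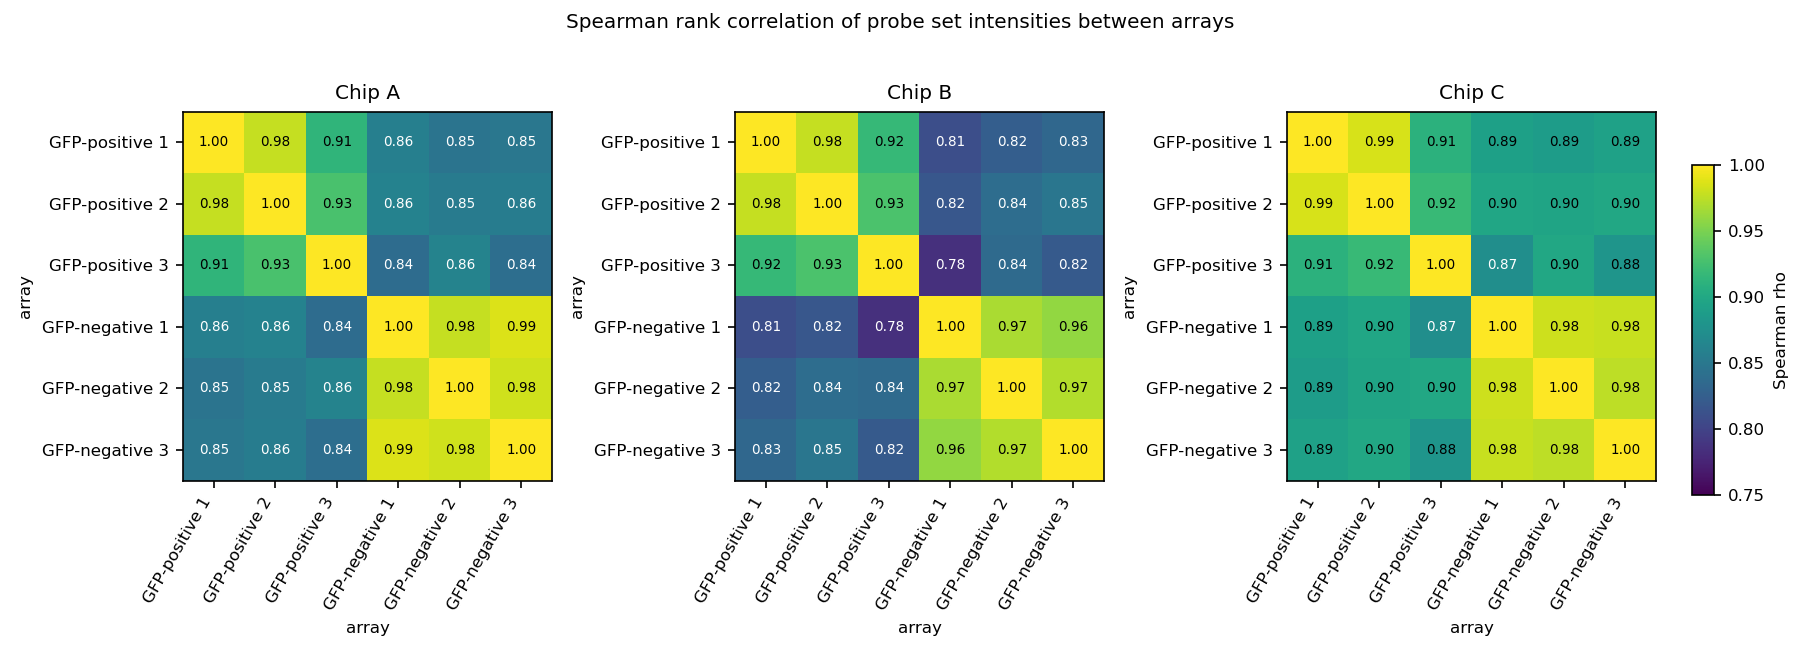
Spearman rank correlation of probe set intensities between the 6 arrays of each chip, with arrays of both populations on both axes and the coefficient in each cell. GFP-positive replicate 3 correlates with GFP-positive replicates 1 and 2 at 0.911 to 0.929, below the 0.960 to 0.987 between the other arrays of 1 population.

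The comparison of GFP-positive with GFP-negative cells asked which transcripts mark the endothelium of the developing retina. On chip A the largest difference among transcripts higher in GFP-positive cells was that of Cldn5, the tight junction protein claudin-5, at 3020.3 ± 618 in GFP-positive against 24.6 ± 3.19 in GFP-negative cells (mean intensity ± SD, n = 3 arrays each, as for all pairs of values here). Its log2 difference was 6.21 (SE 0.16, adjusted p = 2.68e-05, limma), and all log2 differences are GFP-positive minus GFP-negative on the log2 of intensity plus 16, a scale that understates the change of dim probe sets. Cd93, an endothelial surface glycoprotein, followed at 6.02, and Eng, the TGF-beta coreceptor endoglin, at 5.96. Cdh5, which encodes VE-cadherin, rose by 5.29, and Vwf, von Willebrand factor, by 4.88. Lcp1, an actin-bundling protein best known from leukocytes, differed by 4.87, the receptor tyrosine kinase gene Tie1 by 4.78 and Rflnb, a filamin-binding protein, by 4.71. Tek, which encodes the receptor Tie2 whose promoter drove the GFP, was 442 ± 174 against 8.23 ± 1.46, a log2 difference of 4.15 (SE 0.31, adjusted p = 0.000592).

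On chip A the largest difference among transcripts lower in GFP-positive cells was that of Ncam1, a neural cell adhesion molecule, at 90.6 ± 38.6 in GFP-positive against 3239 ± 221 in GFP-negative cells, or -5.00 (SE 0.27, adjusted p = 0.000192). The collagen receptor Ddr1 differed by -4.75, the proneural transcription factor Neurod4 by -4.54, Ndrg2 by -4.45 and the collapsin response mediator Dpysl4 by -4.39. Rlbp1, the retinaldehyde-binding protein of Müller glia, differed by -4.38, Sox2, a transcription factor of retinal progenitors and Müller glia, by -4.37, and the growth cone protein Basp1 by -4.35.

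On chip B, Aplnr, the apelin receptor, differed by 5.96, the mechanosensitive channel Piezo1 by 5.20 and a second Cd93 probe set by 5.20, while Ttyh1 differed by -5.71, the collagen gene Col9a1 by -4.99 and the secreted Wnt pathway modulator Dkk3 by -4.75. On chip C, the endothelial transcription factor Sox17 differed by 5.58, the forkhead factor Foxq1 by 5.31 and the adhesion receptor Adgrl4 by 5.03. The largest losses on that chip were those of Nol4 at -5.58, of Miat, a long non-coding RNA, at -5.10 and of the adhesion receptor Adgrv1 at -4.81. Apart from Tek, which was always included, these probe sets were chosen among those that passed the threshold without overlap between the arrays of the populations.

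Of 12422 probe sets on chip A, 1129 were higher and 1149 lower in GFP-positive cells at an adjusted p under 0.05, and 552 and 543 of them differed at least 2-fold. Chip B had 1191 higher and 1405 lower probe sets of 12411, with 406 and 678 at least 2-fold, and chip C had 403 and 698 of 11868, with 145 and 380 at least 2-fold. The arrays of the 2 populations did not overlap at 37.0% of the probe sets of chip A, 42.8% of chip B and 31.8% of chip C, where chance gives 10%. Over the 3 chips, 15964 genes were measured by a probe set with 1 gene symbol, of which 1961 had a probe set that was higher, 2413 one that was lower and 64 both. The counts changed when single arrays were left out. A fit with 1 array fewer is also less precise, so calls can be lost whichever array is omitted. A call said below to end without an array therefore need not rest on that array. Without GFP-positive replicate 3 they were 1738 and 1731 on chip A, and 1559 higher and 1417 lower on chip C. Without GFP-negative replicates 1, 2 and 3 in turn, the higher count was 693, 721 and 638 on chip A and 141, 145 and 151 on chip C, and the lower count was 710, 876 and 674 on chip A and 417, 454 and 455 on chip C. On chip B the higher count fell to 657 without GFP-positive replicate 2, 682 without GFP-negative replicate 1 and 658 without GFP-negative replicate 2. On chip C the higher count was also 229 without GFP-positive replicate 1 and 176 without GFP-positive replicate 2, and the lower count 411 without the latter. The share of calls that were higher on chip C was 36.6%. It was 31.3%, 30.0% and 52.4% without GFP-positive replicates 1, 2 and 3, and 25.3%, 24.2% and 24.9% without GFP-negative replicates 1, 2 and 3.

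**Figure D2:**
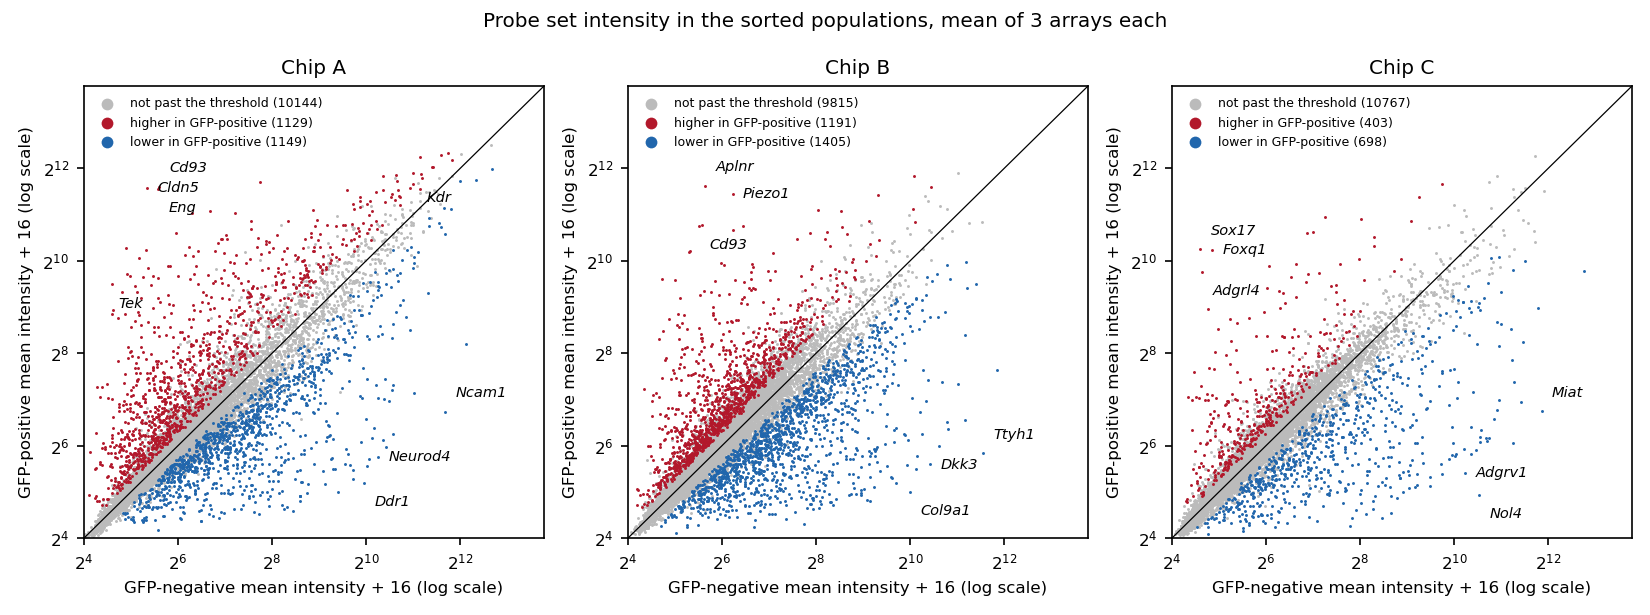
Mean intensity plus 16 of each probe set in GFP-negative (x axis) and GFP-positive cells (y axis), both on log scales, with n = 3 arrays per population, 1 panel per chip; red points are higher and blue points lower in GFP-positive cells at an adjusted p under 0.05, grey points did not pass, and the line marks equal means. The labelled genes with the largest differences lie far from the line, with Cldn5 at 6.21 and Ncam1 at -5.00 on the log2 scale, whereas Kdr lies on it.

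In the endothelial identity list, 21 of 31 measured genes rose in GFP-positive cells and none fell, and 21 rose adjusted over the list alone. Cldn5, Cd93 and Eng led the list. The camera test over the 22 genes on chip A gave an upward shift with a median log2 difference of 2.99 (adjusted p = 6.28e-11, and adjusted p = 0.0998 with an estimated correlation). Plxnd1, the endothelial semaphorin receptor, was 570.5 ± 50.3 against 31.9 ± 1.15, a log2 difference of 3.61 (SE 0.08, adjusted p = 2.68e-05). Some endothelial genes did not pass. Kdr, which encodes VEGF receptor 2, was bright in both populations at 2235 ± 233 against 2245 ± 503 (log2 difference 0.01, SE 0.18), and the adhesion molecule Pecam1 was 50.2 ± 7.19 against 52.6 ± 4.57 (-0.05, SE 0.11). The counts were 22 higher and 1 lower without GFP-positive replicate 3.

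Endothelial transcription factors followed, with 15 of 28 measured genes higher and none lower, or 18 higher adjusted over the list alone. Lmo2, a haematopoietic and endothelial cofactor, was 926 ± 301 against 39.2 ± 3.96, and the SOX factors Sox18 and Sox17 differed by 3.51 and 3.01. Tcf4 did not pass (-0.25, SE 0.22). The list shifted upwards on chip A (median 0.62, adjusted p = 2.03e-07, and adjusted p = 0.0998 with an estimated correlation).

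Genes linked to tip cells, the leading cells of vascular sprouts, were higher for 16 of 22 measured members, 17 adjusted over the list alone. Igfbp3, an insulin-like growth factor binding protein, was 1535 ± 269 against 46.1 ± 3.06, the laminin gene Lama4 differed by 4.04 and the netrin receptor Unc5b by 3.05. The endothelin receptor gene Ednrb was the 1 member that fell (-1.03), a call that ended without GFP-negative replicate 1 (adjusted p = 0.0579). Dll4, the Notch ligand of tip cells, was 70.9 ± 26.2 against 35.9 ± 8.48 and did not pass (adjusted p = 0.0695), but passed without GFP-positive replicate 1 (adjusted p = 0.0455). The tip cell list shifted upwards (median 1.44, adjusted p = 3.22e-07, and adjusted p = 0.0998 with an estimated correlation).

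Arterial genes rose for 9 of 17 members and none fell, with 11 higher adjusted over the list alone. The chemokine gene Cxcl12 was 456 ± 96.6 against 19.8 ± 10.0 and differed by 3.73. Efnb2, the arterial ephrin ligand, was bright in both populations at 1418 ± 403 against 1955 ± 123 and did not pass (-0.50, SE 0.22). Venous genes rose for 8 of 10 members, 9 adjusted over the list alone, among them Vwf, the amino acid transporter Slc38a5 at 3.95 and the matrix protein Tgfbi at 2.67. The venous list also held 1 gene that fell, Vcam1 at -2.13, an adhesion molecule that is also made outside endothelium. Other Vcam1 probe sets on chip A, looked up after the values were seen, were dimmer and did not pass (-0.35 and 0.15). Nr2f2, the transcription factor of venous identity, did not pass (0.43, adjusted p = 0.135) but passed without GFP-positive replicate 3 (0.60, adjusted p = 0.0065). The arterial shift had a median of 1.31 (adjusted p = 0.000674, and adjusted p = 0.172 with an estimated correlation), and the venous shift one of 0.98 (adjusted p = 3.91e-05, and adjusted p = 0.118 with an estimated correlation). In the arterial list 1 member fell without GFP-positive replicate 3. The comparison was between endothelial and other retinal cells, so these rises do not tell tip, arterial and venous cells apart. The lists also overlap, as Sox17 and Unc5b stand in both the tip cell and the arterial list.

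The VEGF and angiopoietin system holds receptors of endothelial cells and their ligands. Of 15 measured genes, 9 rose and 2 fell, also when adjusted over the list alone. Tie1, Tek and the receptor phosphatase Ptprb (2.88) led the rise, whereas the receptor gene Kdr did not pass (0.01). The 2 that fell were Vegfa, the main angiogenic ligand, at 14.3 ± 2.22 against 50.4 ± 11.1 (-1.12, adjusted p = 0.00334), and Vegfb at -0.50, whose call ended without GFP-negative replicate 2 (adjusted p = 0.0578) or 3 (adjusted p = 0.076). The list shifted upwards (median 1.43, adjusted p = 0.00145, and adjusted p = 0.229 with an estimated correlation).

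**Figure D3:**
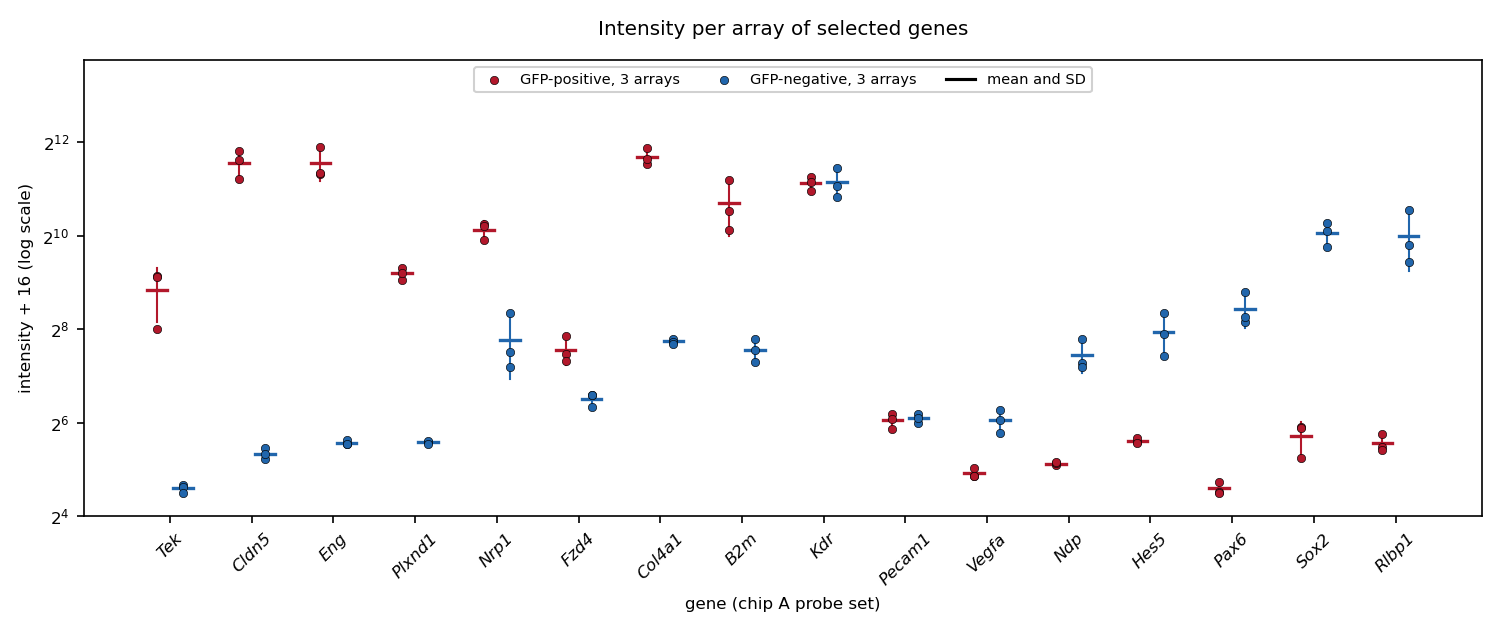
Intensity plus 16 on a log scale (y axis) for 16 genes measured on chip A (x axis); each point is 1 array, red for GFP-positive and blue for GFP-negative cells, with a horizontal bar at the mean and a vertical bar for the SD (n = 3). Tek sits at 442 ± 174 in GFP-positive against 8.23 ± 1.46 in GFP-negative cells, Rlbp1 and Sox2 lie the other way round, and the arrays of Kdr and Pecam1 overlap.

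Signalling pathways of vessel growth had members in both directions. In the Notch pathway 4 of 22 measured genes rose and 5 fell, 5 and 5 adjusted over the list alone. The ligand gene Jag1 rose by 2.17 and the glycosyltransferase gene Mfng by 1.21, whereas Hes5, a target gene in neural progenitors, differed by -2.29, its relative Hes6 by -1.25 and Dtx1 by -1.64. Notch1 did not pass at 1407 ± 316 against 987 ± 114 (0.49, adjusted p = 0.117). Without GFP-negative replicate 3 the count that fell was 3. The camera test gave no shift (adjusted p = 0.517), and the list's median of 0.05 lay opposite to its downward mean and test.

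In the Norrin and Wnt pathway 4 of 30 genes rose and 5 fell, 4 and 6 adjusted over the list alone. Fzd4, the receptor for Norrin on retinal endothelium, was 173 ± 37.6 against 75.1 ± 8.85 (1.04, adjusted p = 0.00768), and Apcdd1, a Wnt target and antagonist, rose by 2.59. Ndp, which encodes Norrin itself, lay the other way at 19.0 ± 0.898 against 159 ± 40.9 (-2.30, adjusted p = 0.000487), as did the receptor gene Fzd5 at -4.45 and Dkk3 at -3.66 on chip A. Ctnnb1, beta-catenin, did not pass (0.22, SE 0.29). The list as a whole showed no shift (adjusted p = 0.787), and its median of 0.01 lay opposite to its downward mean and test. Without GFP-positive replicate 3 the count that fell was 8, and without GFP-negative replicates 2 or 3 the count that rose was 2.

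In the TGF-beta and BMP pathway 5 of 31 genes rose and 4 fell, the same numbers as adjusted over the list alone. Eng led by far, followed by the signal transducer Smad1 at 1.33, and the ligand gene Tgfb2 differed by -2.74. The calls of the receptor gene Acvrl1 (1.31) and of the inhibitor Id4 (-1.77) ended without single arrays, with adjusted p of 0.0631 and 0.099 without GFP-negative replicate 1. Id2 did not pass (-0.75). No shift of the list was called by camera (adjusted p = 0.517), whereas fry called it upwards (adjusted p = 0.0204). The count that rose was 3 without GFP-negative replicate 1 or 3, and the count that fell was 2 without the latter.

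Axon guidance families, which also steer vessels, were divided by member. Of 31 semaphorin, plexin and neuropilin genes, 6 rose and 4 fell, 8 and 4 adjusted over the list alone. Sema3g rose by 3.71, Plxnd1 by 3.61 and the VEGF and semaphorin coreceptor Nrp1, at 1107 ± 145 against 203 ± 95.5, by 2.44. Sema5a differed by -2.65 and Plxnc1 by -1.82. Sema6c did not pass (-0.65, SE 0.84), and without GFP-positive replicate 3, which read it far brighter than the other arrays of its population, it was -1.65 (adjusted p = 0.00428). Without that array 11 members fell. The list showed no shift (adjusted p = 0.261).

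Of 33 Slit, Robo, netrin, Unc5 and ephrin genes, 4 rose and 5 fell, with the same numbers adjusted over the list alone. The receptor genes Unc5b and Robo4, both known from endothelium, rose by 3.05 and 2.29, and the neuronal receptor genes Epha5, Unc5c and Robo2 differed by -4.05, -3.20 and -2.51. The list showed no shift by camera (adjusted p = 0.517), whereas fry called it downwards (adjusted p = 0.00786).

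Rhoj, 1 of the genes always included, was 49.2 ± 9.35 against 36.3 ± 3.16 on chip A and did not pass (adjusted p = 0.155). Without GFP-positive replicate 3 it passed at 0.43 (adjusted p = 0.0206). A second Rhoj probe set on chip B, looked up after the chip A value was seen, was 70.5 ± 6.17 against 27.0 ± 2.80 (1.01, adjusted p = 0.000747).

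The basement membrane is the matrix sheet that endothelial cells share with pericytes. Of 26 measured members 16 rose and 1 fell, 19 and 1 adjusted over the list alone. Col4a1, a chain of collagen IV, was 3293 ± 413 against 198 ± 7.52 (3.94), and the laminin chains Lamb1 and Lama4 differed by 4.32 and 4.04. The member that fell was P4ha1, a collagen prolyl hydroxylase (-1.45), and without GFP-positive replicate 3 there were 3 that fell. Serpinh1, a collagen chaperone, did not pass (1.02, adjusted p = 0.067). The shift on chip A had a median of 0.99 (adjusted p = 7.01e-08, and adjusted p = 0.116 with an estimated correlation).

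Barrier and transport genes encode the junction proteins and carriers of the blood-retina barrier. Of 29 genes 23 rose and none fell, 24 adjusted over the list alone. Besides Cldn5, the iron exporter Slc40a1 was 1694 ± 615 against 71.3 ± 24.4 (4.27) and Slc38a5 was 1090.4 ± 215 against 54.9 ± 1.84. Slc38a3 did not pass (0.04, SE 0.32). The median on chip A was 2.28 (adjusted p = 8.49e-11, and adjusted p = 0.0998 with an estimated correlation). Genes of caveolae rose for 3 of 10 members, 4 adjusted over the list alone, namely Cavin3 at 3.34, Cavin2 at 2.81 and Cav1 at 1.93. The Cav1 call ended without GFP-negative replicate 2 (adjusted p = 0.0558) or 3 (adjusted p = 0.0574), and without GFP-positive replicate 3 the list had 6 higher and 1 lower. Ehd2 did not pass (0.31). The caveolar shift on chip A had a median of 1.93 over 5 genes (adjusted p = 0.00925, and adjusted p = 0.159 with an estimated correlation). On chip B, also with 5 genes, it was not called (median 0.31, adjusted p = 0.375).

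Integrins and adhesion receptors went both ways, with 11 of 32 higher and 5 lower, also over the list alone. Icam2, an endothelial adhesion molecule, rose by 3.38, the junctional protein F11r by 2.72 and the integrin chain Itga1 by 2.65. Ncam1 fell, as did Itgb8 at -3.37. Cdh2, N-cadherin, did not pass (-0.87, adjusted p = 0.114), and passed without GFP-positive replicate 1 (-1.16, adjusted p = 0.0322). The list showed no shift by camera (adjusted p = 0.223), whereas fry called it upwards (adjusted p = 0.00209).

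Antigen presentation and interferon genes rose for 12 of 27 measured members and none fell, 15 adjusted over the list alone. B2m, the light chain of class I molecules, was 1638 ± 632 against 173 ± 31.2 (3.08), the immunoproteasome subunit Psmb8 differed by 3.07 and the class I heavy chain H2-K1 by 2.26. Irf1 did not pass (0.49). The shift had a median of 0.46 (adjusted p = 4.51e-07, and adjusted p = 0.117 with an estimated correlation). Without GFP-positive replicate 3, 1 member fell.

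Cell cycle genes were higher in the GFP-positive population for 23 of 40 members and lower for none, or 30 and 2 adjusted over the list alone. Ccnb2, a mitotic cyclin, was 366 ± 117 against 41.2 ± 4.76 (2.69), the mitotic kinase Aurkb differed by 2.43 and the replication helicase subunit Mcm3 by 2.13. Stmn1, a microtubule regulator also abundant in young neurons, was 1581 ± 290.0 against 2338 ± 212 and did not pass (-0.57, adjusted p = 0.0545). Stmn1 passed without GFP-positive replicate 3 at -0.68 (adjusted p = 0.0248), when 1 member fell. The count that rose was 15 without GFP-negative replicate 2 and 14 without GFP-negative replicate 3. The shift had a median of 0.77 (adjusted p = 6.44e-10, and adjusted p = 0.117 with an estimated correlation).

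Glycolysis genes were lower in GFP-positive cells for 10 of 17 members and higher for 1, or 10 and 3 adjusted over the list alone. Aldoc, an aldolase isoform of neural cells, was 32.9 ± 4.55 against 727 ± 137 (-3.92), the neuronal enolase Eno2 differed by -3.04 and Ldhb by -2.55. The member that rose was Hk1 (0.40), a call that ended without GFP-positive replicate 2 and without each GFP-negative replicate, at adjusted p from 0.0509 to 0.0605. The count that rose was 2 without GFP-positive replicate 1 and 3 without GFP-positive replicate 3. Ldha did not pass at 1449.9 ± 339.6 against 1843 ± 147 (-0.37). The downward shift had a median of -0.63 (adjusted p = 0.000674, and adjusted p = 0.214 with an estimated correlation).

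Müller glia, the radial glia of the retina, had 18 of 22 measured members lower and none higher, also over the list alone. Besides Rlbp1 and Sox2, the transcription factor Sox9 was 54.2 ± 16.2 against 971 ± 229.5 (-3.82). Glul, glutamine synthetase, did not pass (1.03, SE 0.72), and GFP-positive replicate 3 read it at 986 where replicates 1 and 2 read 136 and 156. The list shifted downwards (median -1.17, adjusted p = 7.97e-07, and adjusted p = 0.178 with an estimated correlation).

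Bipolar cell genes were lower for 6 of 12 members, 7 adjusted over the list alone, among them the G protein subunit Gnao1 at -3.78, the rod bipolar kinase Prkca at -3.77 and Scgn, secretagogin, at -2.53. Pcp2 did not pass (-0.81, SE 1.13), and without GFP-positive replicate 3 it was -2.16 (adjusted p = 0.00303). Synaptic and neuronal genes were lower for 9 of 29 members, also over the list alone, including the glutamate receptor subunit Gria2 at -3.48, Snap25 at -2.61 and the complexin Cplx3 at -1.98. Stx3 did not pass (-1.23). The bipolar shift had a median of -0.93 over 8 genes (adjusted p = 0.00344, and adjusted p = 0.362 with an estimated correlation), and the synaptic shift one of -0.16 (adjusted p = 0.00244, and adjusted p = 0.362 with an estimated correlation).

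Amacrine and horizontal cell genes were lower for 5 of 21 members, also over the list alone, among them Neurod4 and Pax6, a master regulator of eye development, at 8.18 ± 2.26 against 331 ± 84.4 (-3.82). The call of Tfap2c (-1.09) ended without GFP-positive replicates 1 and 2 and GFP-negative replicates 2 and 3, at adjusted p from 0.0792 to 0.107. Atp2b1 did not pass (-0.31) and passed without GFP-positive replicate 1 (-0.45, adjusted p = 0.0389). The count that fell was 3 without GFP-positive replicate 2 or GFP-negative replicate 2 or 3. The list shifted downwards (median -0.09, adjusted p = 0.0347, and adjusted p = 0.362 with an estimated correlation), and this call ended without GFP-positive replicate 1 (adjusted p = 0.0733) or GFP-negative replicate 2 (adjusted p = 0.0947).

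Rod photoreceptor genes were lower for 4 of 23 members and higher for 1, or 7 and 1 adjusted over the list alone. Neurod1, a transcription factor of photoreceptors, was 79.4 ± 68.2 against 1009.6 ± 269 (-3.61) and the phototransduction-associated gene Unc119 differed by -1.99. The calls of Sag, rod arrestin (-2.37), and of Rpgrip1, the member that rose (0.58), each ended without GFP-negative replicate 1 (adjusted p = 0.158 and 0.133) and without other arrays. GFP-positive replicate 2 read Neurod1 at 158, where replicates 1 and 3 read 39.6 and 40.4. It read Sag at 271, where they read 65.2 and 72.55. Rpgrip1, in contrast, was lowest among GFP-positive arrays on replicate 2, at 225. A second Rpgrip1 probe set on chip B, chosen after its values were seen, was called the other way (-1.02, adjusted p = 0.0407). Gnb1 did not pass (0.11). The list shifted downwards (median -0.35, adjusted p = 0.0412, and adjusted p = 0.436 with an estimated correlation), a call that ended without GFP-positive replicate 1 (adjusted p = 0.143) or GFP-negative replicate 3 (adjusted p = 0.105). The count that fell was 2 without GFP-positive replicate 1 or GFP-negative replicate 1 or 3, and 7 without GFP-negative replicate 2. No member rose without any 1 array other than GFP-negative replicate 3.

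Cone photoreceptor genes were lower for 2 of 8 members, also over the list alone, the transducin subunits Gnb3 (-3.35) and Gnat2 (-0.60). Thrb did not pass (-0.41) and was -0.90 without GFP-positive replicate 3 (adjusted p = 0.00546), when 3 members fell and 1 rose. Among 20 retinal ganglion cell genes Gap43 fell (-1.02), and Stmn2 (1.77) and Sncg (0.70) were higher, with the same calls over the list alone. Both of the latter calls ended without any 1 GFP-negative replicate, at adjusted p from 0.0506 to 0.0619 for Stmn2 and from 0.101 to 0.123 for Sncg, which also lost its call without GFP-positive replicate 2 (adjusted p = 0.0812). Without GFP-positive replicate 3, 2 ganglion cell members fell. Tubb3 did not pass (-0.41). Camera gave no shift for cones (adjusted p = 0.517) or ganglion cells (adjusted p = 0.63). Fry called the cone list downwards (adjusted p = 0.0192) and did not call the ganglion cell list.

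Astrocytes guide the growing retinal vessels, and their 12 markers split, with 2 higher and 3 lower, also over the list alone. Gja1, connexin 43, was 1172 ± 245 against 70.7 ± 46.2 (3.88) and Nes, nestin, rose by 1.82; both are also known from endothelial cells. Aldoc, the growth factor receptor gene Pdgfra (-3.45) and the lipid-binding protein Fabp7 (-2.89) fell. Aldh1l1 did not pass (-0.05). The astrocyte list showed no shift by camera (adjusted p = 0.664), and its median of 0.02 lay opposite to its downward mean and test. Fry called it downwards (adjusted p = 0.00489).

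Mural and blood cells touch or fill the same vessels. Of 26 pericyte and smooth muscle genes 2 rose and 1 fell, 0 and 1 adjusted over the list alone. The 2 that rose, Tagln2 (1.83) and the proteoglycan Lum (0.28), lost their calls without any 1 GFP-negative replicate, at adjusted p from 0.107 to 0.161, and without GFP-positive replicate 2 at 0.127 and 0.131. Lum also lost its call without GFP-positive replicate 1 (adjusted p = 0.0715) or 3 (adjusted p = 0.0577), and so without each array in turn. Zic1, a zinc-finger transcription factor, fell (-3.62). The pericyte receptor gene Pdgfrb was 26.5 ± 6.25 against 32.9 ± 4.62 and did not pass (-0.21, SE 0.13). Mylk did not pass (0.62, SE 0.89) and was -0.45 without GFP-positive replicate 3 (adjusted p = 0.0312), when 4 members fell and 1 rose. The list showed no shift (adjusted p = 0.838).

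Of 31 microglia and macrophage genes 5 rose and none fell, also over the list alone. Lcp1 was 1047 ± 194 against 20.1 ± 4.94, the NADPH oxidase subunit Cyba differed by 2.67 and the lysosomal protein Laptm5 by 1.56. The other members that rose, Fcer1g (1.50) and C1qb (0.78), were chosen after their values were seen. Ptprc, the pan-leukocyte antigen CD45, was 40.1 ± 14.6 against 38.0 ± 3.65 (0.03, SE 0.19), and Lyz1 did not pass (0.20). The list's shift was not called (adjusted p = 0.0884) but was called without GFP-positive replicate 2 (adjusted p = 0.0239) and with brighter probe sets only (median 0.24, adjusted p = 0.0300), with adjusted p = 0.553 for all arrays with an estimated correlation, and without GFP-positive replicate 3 there were 2 members that fell.

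No member of the erythroid and platelet list passed among 18 measured, while 2 rose and 1 fell without GFP-positive replicate 3 and 1 rose without GFP-positive replicate 2. Of 16 lymphoid genes only Ms4a1 rose (0.38), and this call ended without each array in turn except GFP-positive replicate 3, at adjusted p from 0.0509 to 0.0857. Nkg7 did not pass (0.49) and was 0.63 without GFP-positive replicate 3 (adjusted p = 0.00705), when 2 lymphoid members rose and 1 fell. Pigment epithelium and lens genes rose for 2 and fell for 2 of 28 members, or 1 and 2 adjusted over the list alone. Bfsp1, a lens filament protein, differed by -0.75, and the calls of Dct, a melanin synthesis enzyme (1.24), and Crybb3 (0.45) ended without each GFP-negative replicate, at adjusted p from 0.0527 to 0.0636 and from 0.0886 to 0.128. Crybb3 also lost its call without GFP-positive replicate 2 (adjusted p = 0.146) or 3 (adjusted p = 0.071), and 4 members fell without the latter. Cryaa did not pass (0.65, SE 0.47). Camera called none of the 3 lists, with adjusted p of 0.567, 0.217 and 0.664, and the median of the pigment and lens list, 0.04, lay opposite to its downward mean and test.

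Dissociation can induce immediate early genes. Of 30 such genes 5 were lower in GFP-positive cells and 1 was higher, or 10 and 3 adjusted over the list alone. Egr1, an immediate early transcription factor, was 383 ± 5.67 against 1504 ± 397 (-1.90), and the chaperone Hsp90aa1 differed by -1.66. The call of Fosb (-1.84) ended without any 1 GFP-negative replicate, at adjusted p from 0.0625 to 0.126, and that of Nr4a1 (1.15) without GFP-negative replicate 2 or 3, at adjusted p of 0.0624 and 0.0745. The heat shock gene Hspa1a was bright in both populations and did not pass (-0.37). The count that fell was 9 without GFP-positive replicate 3, 3 without GFP-negative replicate 1 and 2 without GFP-negative replicate 3, and the count that rose was 3 without GFP-positive replicate 1 and 2 without GFP-positive replicate 3. The list showed no shift (adjusted p = 0.517).

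**Figure D4:**
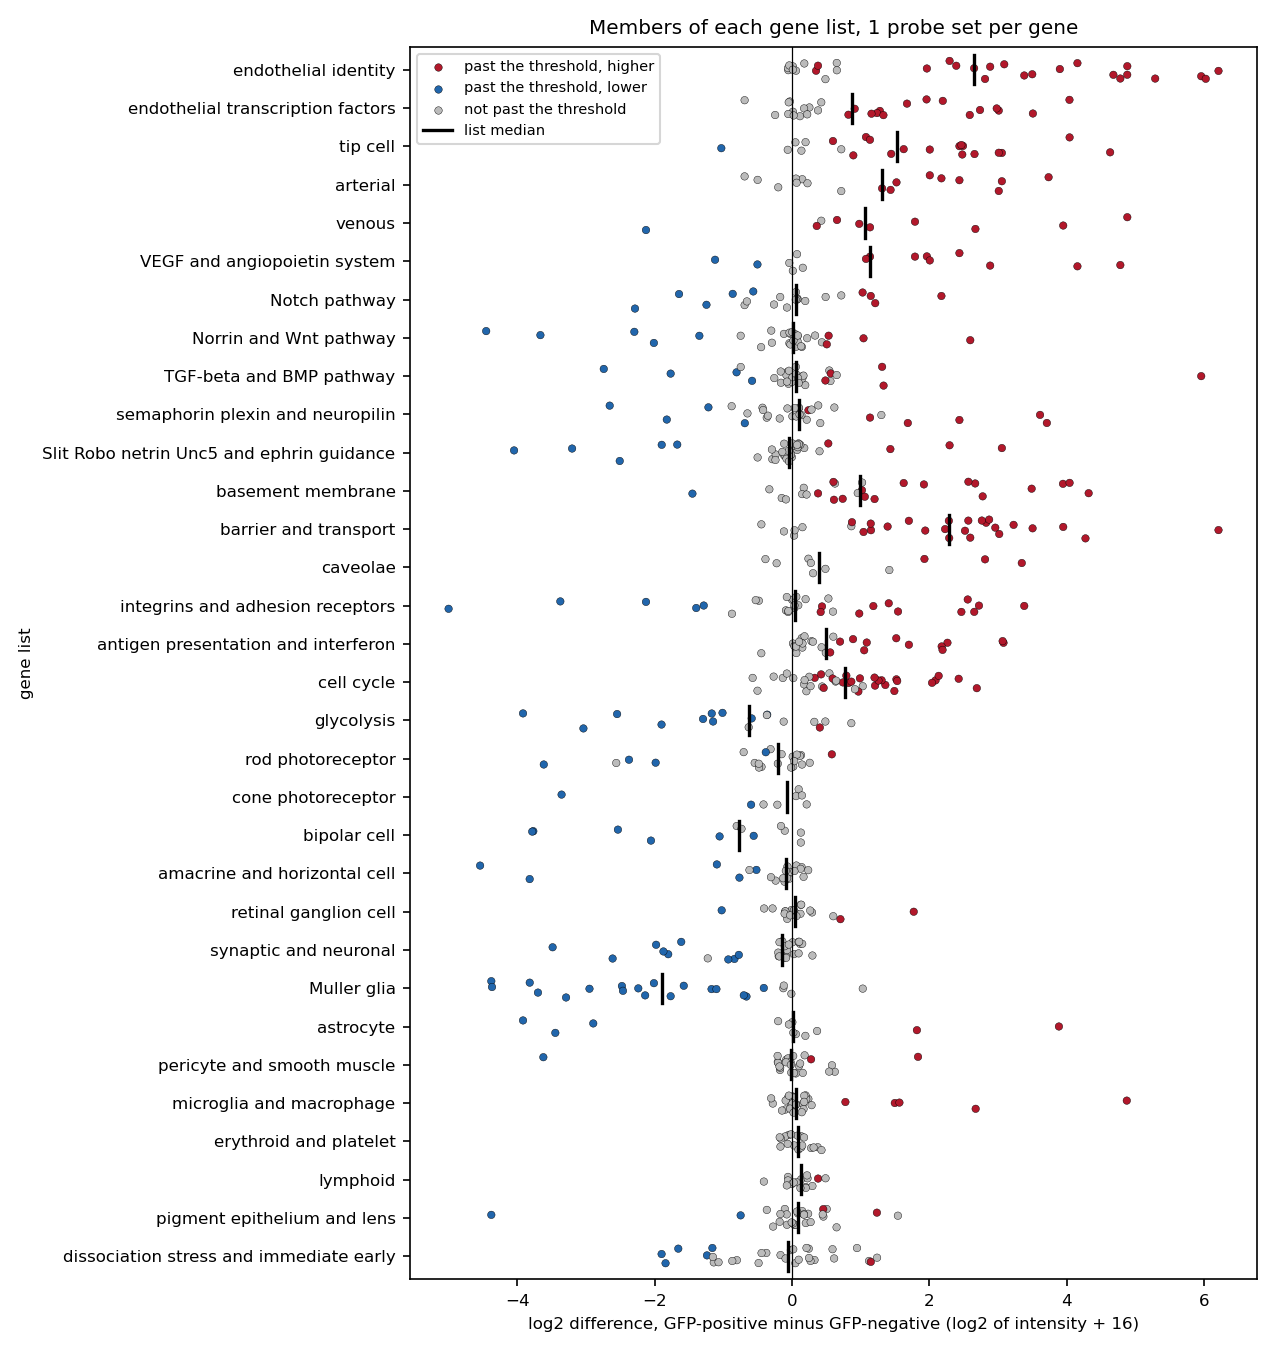
The log2 difference, GFP-positive minus GFP-negative, of each measured member (points, x axis) of the gene lists reported here (y axis), 1 probe set per gene, with the list median as a vertical bar; red and blue points passed an adjusted p of 0.05 and grey points did not. The members of the barrier and transport list lie mostly to the right, with 23 of 29 higher, and those of the Müller glia list mostly to the left, with 18 of 22 lower.

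Camera with its preset correlation called 17 of the 33 lists on chip A, and with a correlation estimated from these arrays it called none, the smallest adjusted p being 0.0998. On chip B camera called 7 of 21 lists, and on chip C 6 of 23, and none of these calls held with an estimated correlation, where the smallest adjusted p was 0.0901 on chip B and 0.301 on chip C. The estimated correlation was -0.120 for caveolae on chip A and 0.00123 for barrier and transport on chip B. Both lay below the preset 0.01, yet both calls were lost. Correlation between genes therefore cannot alone account for the lost calls. Endothelial identity, endothelial transcription factors, tip cell and barrier and transport were called upwards on each of the 3 chips, and Müller glia downwards on chips A and B, all with the preset correlation. Of the lists called on chip A, basement membrane, caveolae and amacrine and horizontal cell were tested and not called on chip B, and arterial, antigen presentation and interferon, bipolar cell and synaptic and neuronal were tested and not called on chip C. The chips repeat some genes through different probe sets, which agreed in part. Between chips A and B the log2 differences of 2119 shared genes had a Spearman correlation across genes, which are not independent of each other, of 0.323, and 170 of the 182 genes called on both chips had the same direction. Chips A and C shared 2049 genes (0.267), with 119 of 123 in the same direction, and chips B and C 2287 genes (0.263), with 103 of 114. The replicate numbers repeat on each chip and GFP-positive replicate 3 stood apart on all 3, so the chips may have carried the same RNA. Calls and agreement across chips are therefore not independent replication.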

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

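Array weights were chosen after the data were seen; all other alternatives were fixed before. Tek was higher in GFP-positive cells under every alternative run, with log2 differences from 2.74 to 5.50. Among 160 named probe sets, 126 of them called, none of the settings counted reversed the direction of a called one. Between 0 and 16 calls were lost and between 0 and 10 gained per setting counted, the most lost without GFP-negative replicate 3 and the most gained with array weights. An adjusted p under 0.01 and a minimum of 2-fold were not among the settings counted. The former ends more of these calls than any setting counted. With array weights chip A had 2155 higher and 1842 lower probe sets, chip B 2299 higher and chip C 2320 and 1604. At an adjusted p under 0.01 the counts were 593 and 560 on chip A, 503 and 801 on chip B and 120 and 338 on chip C, and with a minimum of 2-fold they were 552 and 543, 406 and 678, and 145 and 380; both settings are stricter by construction. Without probe sets that can match several transcripts chip C had 239 higher and 414 lower, from fewer probe sets tested. Leaving out 1 array at a time, the higher count ranged from 638 to 1738 on chip A, 657 to 1473 on chip B and 141 to 1559 on chip C, and the lower count from 674 to 1731 on chip A and 411 to 1417 on chip C; the highest values were those without GFP-positive replicate 3. Quantile normalization, median centring, both other pseudocounts, brighter probe sets, limma-trend and adjustment over all chips left every count within 1.5 times. Of the calls 2164 of 2278 on chip A, 2348 of 2596 on chip B and 952 of 1101 on chip C were shared with quantile normalization.

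Deviations of same-numbered arrays from their population means correlated at 0.298, -0.287 and -0.152 on chip A and 0.274, -0.340 and -0.156 on chip B. On chip C they correlated at 0.172, -0.408 and -0.347. These values cannot decide whether the replicate numbers pair the arrays, because the deviations within a population sum to 0. On chip A those of GFP-positive replicate 3 correlated at -0.838 and -0.737 with those of GFP-positive replicates 1 and 2. Between the populations, GFP-positive replicate 3 and GFP-negative replicate 2 had the highest correlation on each chip, at 0.400, 0.447 and 0.488 on chips A, B and C. A factor shared by these arrays was not tested. With the replicate number as a block the counts were 843 higher and 855 lower on chip A, 868 and 1231 on chip B and 187 and 454 on chip C. With an estimated inter-gene correlation camera called 0 of 33 lists on chip A, against 17 with the preset one, and fry called 23; other settings called 14 to 18. The rod photoreceptor list was not called with quantile normalization (adjusted p = 0.0549), brighter probe sets only (0.0906), the replicate block (0.0555) or without probe sets that can match several transcripts (0.0509), and the amacrine and horizontal cell list was not called in the last of these (0.0509) or with array weights (0.0518). The agreement between chips A and B, A and C, and B and C rose to 0.794, 0.871 and 0.732 over genes called on both chips, as selection on a call makes likely, and to 0.436, 0.424 and 0.342 over brighter probe sets. Where no cause is named above, the cause was not tested. Limits of these values include the number of arrays, their dependence on single arrays such as GFP-positive replicate 3 and, for dim probe sets, signal over background, which was not analysed here.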

Other observations

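Gene families that share a symbol stem, grouped and tested after the data were seen, gave 4 further groups by camera. On chip A 6 of 9 annexins, calcium-dependent membrane-binding proteins, were higher in GFP-positive cells, with a family median of 2.50 (adjusted p = 0.0108 over 260 families, and adjusted p = 0.998 with an estimated correlation). Anxa3 was 622.6 against 12.1 (log2 difference 4.44, SE 0.27), Anxa1 differed by 3.43 and Anxa2 by 3.07, whereas Anxa8 (-0.03) and Anxa10 (-0.05) did not pass. On chip B 5 of 6 Gimap genes, GTPases best known from lymphocytes, were higher, with a median of 1.94 (adjusted p = 0.0124 over 192 families, and adjusted p = 0.966 with an estimated correlation). Gimap8 differed by 3.53 and Gimap6 by 3.47, and Gimap7 did not pass (0.10). Chip A held Gimap4 at 3.65 (adjusted p = 2.68e-05) and Gimap1 at 3.08 (adjusted p = 7.25e-05).

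Smaller shifts were seen in 2 other families. On chip A 6 of 16 ribosomal proteins of the large subunit with the stem Rpl were higher and none lower, with a median of 0.31 (adjusted p = 0.025, and adjusted p = 0.998 with an estimated correlation), Rpl6 at 1.49 and Rpl41 at 0.86 among them. On chip B 7 of 13 histone lysine demethylases with the stem Kdm were lower and none higher, with a median of -0.43 (adjusted p = 0.0124, and adjusted p = 0.966 with an estimated correlation), led by Kdm7a at -1.17 and Kdm5c at -1.06, but the family was not called on chip A (3 of 7 lower, adjusted p = 0.566) or chip C (none of 7 lower, adjusted p = 0.907), nor was Rpl on chip C (1 of 6 higher, adjusted p = 0.907). Whether these small shifts hold under another scaling was not tested.

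Of the tests below, those of normalization, a ceiling of the intensity scale, the second Kdr probe set, the level of Pecam1, microglia and other groupings of the arrays were chosen after the result was seen. GFP-positive replicate 3 departed from replicates 1 and 2 on every chip, with 141, 168 and 136 probe sets at least 4-fold brighter and 2, 0 and 3 at least 4-fold dimmer on chips A, B and C. Another scaling of that array cannot account for this, because its highest rank correlation with the other GFP-positive arrays, 0.929, lay below the lowest of the other pairs, 0.960, and scaling leaves ranks as they are. Retinal cells in that sort, in the mix of the GFP-negative arrays, are argued against for most of the raised probe sets. Of the 445, 77.5% exceeded the highest GFP-negative array at least 2-fold, although on chip C 49.3% did. A single cell type diluted in that mix could exceed it, so the test cannot decide on such a type. A signal specific to single probe sets is a candidate explanation. The 285 probe sets of the same genes that were not themselves raised 4-fold had a median rise of -0.000645. For genes called at least 4-fold higher in GFP-positive cells, the probe sets that did not meet that bound had a median of 0.47. Leaving out raised probe sets lowers both medians, so they cannot show how many genes rose in several probe sets. What would produce a signal specific to single probe sets stays open, and no biological explanation was tested.

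Kdr, an endothelial receptor gene, was equally bright in both populations, and Pecam1 was at a similar level in both; Kdr transcript in GFP-negative retinal cells was not tested. The planned test of saturation was void, because the 49 called probe sets of chip A that reached the Kdr level in a population could be dim in the other. A ceiling of the scale at that level is argued against, since 13 of the 25 other probe sets at or above it in both populations were called, by up to 1.07, but saturation of the Kdr probe set alone stays open. Whether the Kdr probe set reads other RNA stays open: the only other Kdr probe set, on chip C, differed by -0.13, but its level, at the 50.8 percentile of its chip, may be background, and the rule was tightened from the 50 to the 60 percentile after this was seen. For Pecam1 a dim probe set may be the reason, its level being at the 54.8 percentile, under a bound of 60 chosen when the level was known, although 16.6% of probe sets between the 50 and 60 percentiles were called.

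Lcp1, known from leukocytes, rose in GFP-positive cells with Cyba, Laptm5, Fcer1g and C1qb, and microglia or macrophages carried along in the sort on GFP could be a source. For Lcp1 this stays open: 8 abundant microglial transcripts, picked afterwards from the fixed list (Ctss, C1qa, C1qb, C1qc, Tyrobp, Csf1r, Lyz2 and Cx3cr1), had a median log2 difference of 0.0303 with an SD of 0.27 against 4.87 for Lcp1, but most were dim. Their probe sets lay from the 17.4 percentile for Lyz2 to the 79.7 for Csf1r, and only C1qb was called. For Cyba, Laptm5, Fcer1g and C1qb, with a median of 1.53, a share of such cells cannot be told apart from expression in endothelial cells for the same reason. Expression of these genes in endothelial cells was not tested.

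With 3 arrays against 3 there are 10 splits of the 6 arrays of a chip, so a share under 0.05 cannot be reached. The real split called 2278, 2596 and 1101 probe sets on chips A, B and C, and the highest of the 9 other splits called 0 on each chip, so that 1 of the 10 splits, the real one, gave as many. Every other split puts arrays of both populations on each side, so the population differences widen the spread and few calls could arise. The comparison therefore does not measure false calls in the real split.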
